A study of Mus musculus with 6 samples.

How the data were processed

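Total RNA of the medial prefrontal cortex of 6 mice was labelled from 500 ng per sample with the Affymetrix 3′ IVT Express kit and read on Affymetrix Mouse430_2 arrays, per the labels' protocols. The deposited values are log2 expression values per probe set, 1 column per mouse and none pooled. R 2.15.1 and GCRMA 2.28.0 are listed, per the submitters' processing notes. GCRMA corrects the background by probe sequence, normalizes between arrays and summarises probes into probe sets; any later filter is not given in the sources used here. The values ran from 0.99 to 14.7 on the log2 scale and were used as the authors deposited them. Because quantiles are made nearly equal between arrays, a change of total RNA content cannot be seen, and values near the floor are compressed. All value columns were used, and no 2 columns were identical. Every array came from a separate mouse, so p-values of single probe sets rest on the spread between mice, moderated over all probe sets.

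The table held 45101 probe sets, of which 64 were array controls. The platform annotation gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9147. Of the single-gene probe sets, 34754 matched by Entrez identifier to a reference gene table of assembly GRCm38.p6, which was used for names only, since no build is named for the values. No coordinates are given. Probe sets with several or no symbols were tested but not named.

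Probe sets were kept if the log2 value exceeded 4 on at least 3 of the 6 arrays, and the array controls were left out, which left 25381 or 56.4% of the others. ZnR was compared with control in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, 2-sided, with Benjamini-Hochberg adjustment over all probe sets kept and a threshold of 0.05. No covariate was used, since mouse numbers differ between diets and pair nothing. Errors of log2 differences are moderated standard errors. A fold is 2 raised to the log2 difference.

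For gene lists, each gene was represented by its probe set with the highest mean over all arrays among kept single-gene probe sets, which gave 11749 genes. The 17 pathway and 14 cell type lists held 470 entries, of which 422 had a probe set. The cell type lists cover cells of cortex and of neighbouring tissue that a dissection could hold. No erythroid marker passed the filter, so 30 lists of at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over all lists together. Camera compares a list with all other genes. Its p-values at the preset correlation judge a list against the spread over genes rather than between mice. Correlations were also estimated per list. Standard errors of list means are over mice.

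Genes were named by a rule. It took up to 12 genes higher and 12 lower past the threshold, largest difference first, with no overlap between diets; the up to 3 members of each list with the smallest p; and 18 genes fixed by name for dopamine, histone acetylation, activity and zinc. It gave 117 genes. Lists, tests, the naming rule and most alternatives were fixed before the data were examined. The alternatives covered the level filter, renormalization, the variance prior, array weights, each mouse left out, the unit counted, the moderation and the list test. Splitting on the 18S signal, blocking on consecutive mouse numbers, and 4 further lists, were chosen after seeing the data. Robust variance estimates used statmod 1.5.0, with lists then tested by limma's cameraPR on the moderated statistics.

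Both tests were tested on simulated data with the real means and residual spread. Of 50 probe sets changed by each size, 15 were recovered at a log2 change of 0.5, 46 at 1, 47 at 1.5 and 50 at 2, with 6 false calls among 25381 probe sets. A list moved by 0.5 was called in 50 of 50 draws, and 7 of 1400 unchanged lists were called. Where unchanged genes of a list shared a correlation of 0.3, the preset correlation called 319 of 1500 lists and the estimated correlation 0. The moved list was tested with the preset correlation only. Whether the estimated correlation can call a true shift on these arrays was not simulated. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.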

Results

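Gene expression was measured in the medial prefrontal cortex of 6 male mice of the inbred strain 129S1/SvImJ, aged 8 to 10 weeks. The medial prefrontal cortex is a frontal brain area involved in the learning and suppression of fear. The tissue of both hemispheres was taken 2 h after fear extinction training, in which a feared cue is presented repeatedly without its outcome. Of these mice, 3 were on a control diet (mice 1, 5 and 9) and 3 on a diet that the labels call ZnR and describe as a zinc diet (mice 3, 7 and 11). The composition of that diet is not given in the sources used here. Each mouse gave 1 Affymetrix Mouse430_2 array, on which a gene is read by 1 or more groups of short probes called probe sets. The series title names histone deacetylase inhibition, dopamine and lasting fear inhibition, and the comparison asks how the prefrontal transcripts of ZnR mice differed from those of control mice. The number of arrays limits the precision of every value below.

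The arrays were alike in distribution, as the normalization makes them, with medians over all probe sets between 4.46 and 4.52 log2 units. Arrays of the same diet correlated across probe sets at 0.991 to 0.995 and arrays of different diets at 0.988 to 0.992. The first principal component held 39.5% of the variance and placed all 3 ZnR arrays on one side and all 3 control arrays on the other. The control probe sets for 18S ribosomal RNA split the arrays in another way. Their mean was 9.09 in control mouse 1 and 8.44 in ZnR mouse 3, against 10.9 to 12.4 in the other 4 mice. This pair of arrays, with 1 mouse of each diet, was treated as a possible batch. The labels also name the array file of control mouse 1 by another scheme than those of the other 5, and a batch of that mouse alone cannot be told apart from the mouse.

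Of 25381 probe sets tested, 117 were higher and 256 were lower in ZnR mice, 373 in all or 1.47%. The clearest change was a fall of Arhgap15, which encodes a GTPase-activating protein for Rac, from 7.53 ± 0.12 to 5.19 ± 0.08 log2 units (SD, n = 3 per diet). It was 5.05-fold lower in ZnR mice (log2 difference -2.34 ± 0.10 SE, limma adjusted p = 0.000459). Bdnf, which encodes brain-derived neurotrophic factor, was 2.29-fold lower (-1.19 ± 0.10 SE, adjusted p = 0.00624), and Slc30a3, the transporter that loads zinc into synaptic vesicles, was 2.26-fold lower (-1.17 ± 0.12 SE, adjusted p = 0.016). The chloride channel gene Clic6 rose 2.89-fold (1.53 ± 0.26 SE, adjusted p = 0.0433). Its other probe set rose less (0.59 ± 0.09 SE, adjusted p = 0.0325), so the size of this rise depends on the probe set. The dopamine receptor gene Drd2 rose 1.86-fold (0.89 ± 0.16 SE, adjusted p = 0.046).

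Among genes past the threshold, most of the largest changes were falls. After Arhgap15 the largest were in Rasl10a (log2 difference -1.67), Cpne9 (-1.52), Cbln2 (-1.50), Smoc2 (-1.48), Tnnc1 (-1.48) and Rtn4rl2 (-1.46). Cabp1 (-1.45), the neuropeptide gene Adcyap1 (-1.44), the corticotropin-releasing hormone binding protein gene Crhbp (-1.42), Rasl11b (-1.35) and Exph5 (-1.30) followed. Of the genes past the threshold, the largest rises after Clic6 were in Tmem212 (1.44), Ecel1 (1.18) and the transcription factor gene Isl1 (1.13). The ciliary dynein gene Dnaic2 (1.08) and the neurokinin receptor gene Tacr3 (1.04) came next. Sh3rf2, Prima1, 1700094D03Rik, G630016G05Rik, Cfap126 and Serpinb1b rose by 0.97 to 1.01, though Sh3rf2 (adjusted p = 0.0511) and Prima1 (0.0514) did not pass after renewed quantile normalization. Other probe sets of 1700094D03Rik measured 0.55 (adjusted p = 0.0417) and 0.20 (0.484). That of G630016G05Rik measured 0.31 (0.335). All 24 passed the threshold (adjusted p from 0.000459 to 0.0469) with no overlap between the mice of the diets, since the naming rule required both. A difference of at least 2-fold was reached by 17 of the probe sets that rose and 65 of those that fell, and 34 of the 373 had no single gene symbol. Over all probe sets tested, 6021 or 23.7% had no overlap between the diets, where chance gives 10%.

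**Figure D1:**
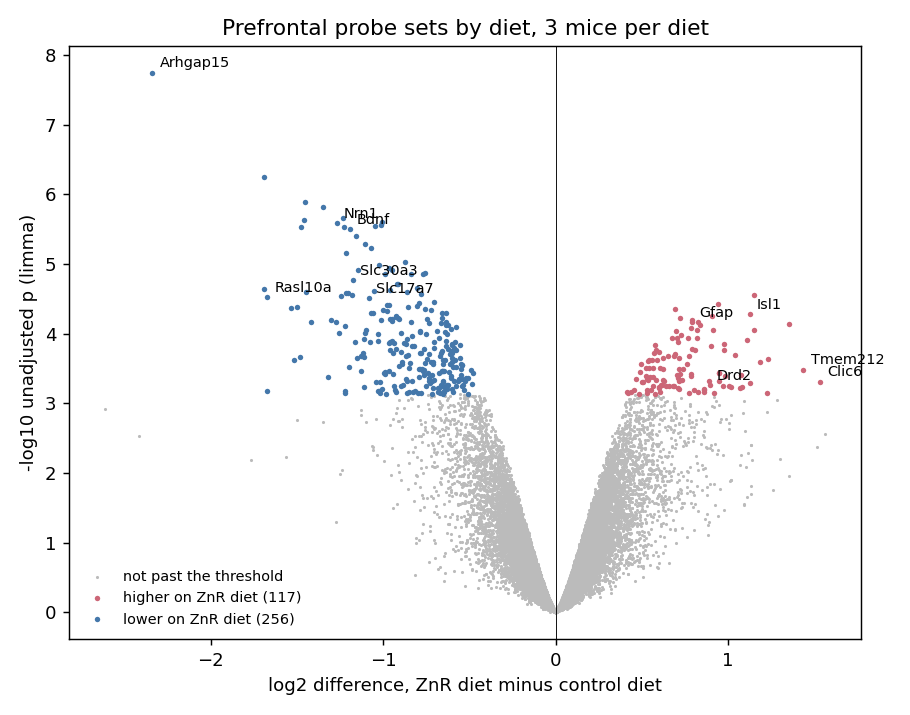
Log2 difference between diets (ZnR minus control, horizontal axis) against -log10 of the unadjusted limma p (vertical axis) for each of the 25381 probe sets tested, 3 mice per diet; coloured points passed the adjusted threshold and some named genes are labelled. The 256 lower probe sets outnumber the 117 higher ones, and Arhgap15 stands apart at -2.34.

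The count of 373 depended on every mouse. It was 101 without control mouse 1, 1 without control mouse 5, 77 without control mouse 9, 18 without ZnR mouse 3, 109 without ZnR mouse 7 and 21 without ZnR mouse 11, and it was 550 with the low-18S pair as a block and 1 without that pair. Of the 373, 360 were among the 550. Among the 40 named genes past the threshold, 20 passed without control mouse 1, 1 without control mouse 5, 16 without control mouse 9, 8 without ZnR mouse 3, 20 without ZnR mouse 7 and 9 without ZnR mouse 11, while 39 passed with the block. Arhgap15 alone passed in all 6 fits that left out a mouse. The 12 that passed in none were Dnaic2, Sh3rf2, 1700094D03Rik, Cfap126, Cpne9, Drd2, Nr4a2, Ptgs2, Nrgn, Neurod6, Mef2c and Gpr6. None of the 40 changed direction. That was fixed in advance, since all 373 probe sets past the threshold had no overlap between the mice of the diets.

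Genes of cortical excitatory neurons were lower in ZnR mice. The list test gave camera adjusted p = 5.21e-07, and adjusted p = 0.204 with an estimated correlation (alternatives ranged from 1.87e-18 to 0.204). Of the 7 measured markers, 6 were lower on average and 1 higher. Of the 7, 5 fell and 2 did not pass the test. The list mean differed by -0.73 ± 0.08 log2 units (SE over mice, n = 3 per diet). It was -0.93 within the low-18S pair and -0.63 between the other mice. In the same arrays, markers of ventricle-lining cells were higher by 1.07 and striatal markers by 0.51. The neuritin gene Nrn1 fell 2.41-fold (-1.27 ± 0.10 SE), the vesicular glutamate transporter gene Slc17a7 fell 2.12-fold (-1.08 ± 0.12 SE) and the transcription factor gene Neurod6 fell 1.78-fold (-0.83 ± 0.12 SE). The others that fell, named after their values were seen, were Neurod2 (-0.84 ± 0.14 SE) and Tbr1 (-1.02 ± 0.18 SE). The same 5 passed when adjusted over the list alone.

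Synaptic vesicle genes moved the same way. The list mean was -0.34 ± 0.05 (SE over mice; -0.43 within the low-18S pair and -0.29 between the other mice), with adjusted p = 1.61e-08 and adjusted p = 0.287 with an estimated correlation (alternatives ranged from 3.61e-16 to 0.287). All 16 measured members were lower on average, 2 of them past the threshold over all genes, and 7 fell when adjusted over the list alone. These were led by the syntaxin gene Stx1a (-0.99 ± 0.10 SE, adjusted p = 0.0137) and Slc17a7, which the excitatory neuron list also holds, while Rims1 (-0.48 ± 0.09 SE) had adjusted p = 0.0513, and its other probe set fell (-0.59 ± 0.09 SE, adjusted p = 0.0292). Markers of the upper cortical layers were lower as well, with a mean of -0.28 ± 0.05 over 7 genes (-0.17 within the low-18S pair, -0.34 between the other mice) and adjusted p = 0.00225, and adjusted p = 0.287 with an estimated correlation (alternatives ranged from 1.86e-05 to 0.287). Of these, Mef2c fell (-0.51 ± 0.09 SE, adjusted p = 0.0423) and 6 did not pass, with 4 past the threshold adjusted over the list alone. On average 6 were lower and 1 higher. Lamp5 measured -0.39 and Lmo4 -0.41. The 8 deep-layer markers did not pass as a list (mean 0.01, median -0.06, test directed lower, adjusted p = 0.735). Foxp2, one of them, measured 0.65 ± 0.20 with adjusted p = 0.161. The 4 deep-layer markers that striatum is not known for, a choice made after the data were seen, measured -0.26 ± 0.19 (SE over mice). They lay 0.0235 ± 0.24 above the upper-layer list, so a difference between deep and upper layers was not shown.

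Immediate early genes, which neurons switch on after activity, were lower as a list, with 3 of 33 measured members past the threshold and 30 not. The list test gave adjusted p = 1.86e-05, and adjusted p = 0.532 with an estimated correlation (alternatives ranged from 5.85e-14 to 0.532). The list mean of -0.34 ± 0.27 (SE over mice) was within 2 standard errors of 0. Within the low-18S pair it was -0.03, and between the other mice it was -0.49. It was -0.57 without ZnR mouse 3 and -0.18 without ZnR mouse 11. In the same arrays the excitatory neuron markers were lower by a mean of -0.73 ± 0.08. The 3 members past the threshold were Bdnf, the nuclear receptor gene Nr4a2 (-1.20 ± 0.19 SE, adjusted p = 0.0368) and the cyclooxygenase gene Ptgs2 (-0.98 ± 0.18 SE, adjusted p = 0.04999, and 0.0539 with the low-18S pair as a block). Adjusted over the list alone, 4 passed, all lower. The common activity markers did not pass: Fos measured -0.67 ± 0.50, Arc -0.53 ± 0.63, Egr1 -0.29 ± 0.18 and Npas4 -0.07 ± 0.52 (SE). Without ZnR mouse 3 Fos measured -1.21, Arc -1.23, Egr1 -0.48 and Npas4 -0.68, while without ZnR mouse 11 Fos measured -0.31 and Arc -0.17, without ZnR mouse 7 Egr1 measured -0.17 and without control mouse 1 Npas4 measured 0.26.

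Dopamine signalling genes were higher in ZnR mice. The list mean was 0.39 ± 0.09 (SE over mice; 0.38 within the low-18S pair and 0.39 between the other mice), with adjusted p = 0.00122 and adjusted p = 0.448 with an estimated correlation (alternatives ranged from 2.79e-05 to 0.448). Of 14 measured members, Drd2 rose and 13 did not pass over all genes, while 7 rose when adjusted over the list alone. Drd2 did not pass in any of the 6 fits that left out a mouse, with differences from 0.75 without control mouse 9 to 1.01 without control mouse 1 and adjusted p up to 0.146. The D1 receptor gene Drd1 measured 0.48 ± 0.14 (adjusted p = 0.14), the G protein gene Gnal 0.42 ± 0.09 (adjusted p = 0.0636), the adenylyl cyclase gene Adcy5 0.41 ± 0.11 (adjusted p = 0.118) and Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, 0.61 ± 0.18 (adjusted p = 0.139). Th, which encodes the enzyme that makes the dopamine precursor, measured 0.02 ± 0.19. This list was chosen from the series title, which may itself rest on these samples, so its direction is not independent evidence.

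Markers of striatal medium spiny neurons, the main neurons of a region next to the dissected cortex, moved with the dopamine genes. All 12 measured markers were higher on average, with a list mean of 0.51 ± 0.16 (SE over mice; 0.44 within the low-18S pair and 0.55 between the other mice) and adjusted p = 2.97e-05, and adjusted p = 0.371 with an estimated correlation (alternatives ranged from 1.06e-07 to 0.371). The receptor gene Gpr6 rose 1.49-fold (0.58 ± 0.08 SE, adjusted p = 0.0275) and Drd2 rose, while 10 did not pass, with 7 past the threshold adjusted over the list alone. Drd1, Drd2, Ppp1r1b and Rgs9 are in both lists. Without them the dopamine list mean was 0.26 over 10 genes, none past the threshold over all genes and 4 higher adjusted over the list alone. The list test then gave adjusted p = 0.0429, and adjusted p = 0.458 with an estimated correlation. Only genes in both lists were left out, and others expressed in striatum may remain. This mean therefore does not separate dopamine genes from striatal tissue.

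**Figure D2:**
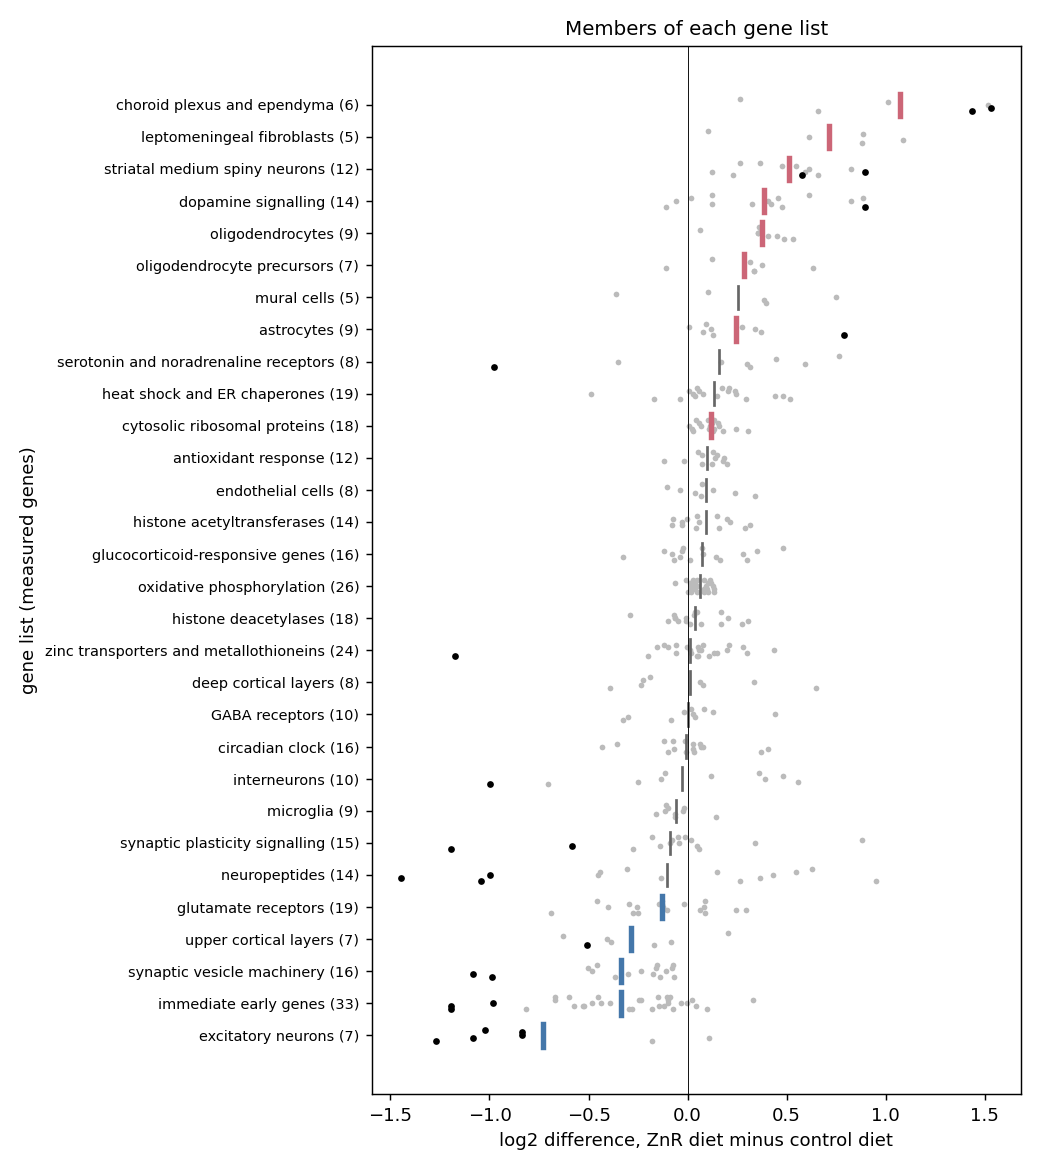
Log2 difference between diets (ZnR minus control) of every measured gene in the 30 lists tested, 1 row per list with its number of genes, from 3 mice per diet. Points are genes, black where they passed the threshold, and bars are list means, coloured and thick where the list test passed; excitatory neuron genes lie lowest at a mean of -0.73 and choroid plexus and ependyma genes highest at 1.07.

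Genes of the cells that line the ventricles were higher in ZnR mice by the widest margin of any list. The 6 measured markers of choroid plexus and ependyma had a mean of 1.07 ± 0.28 (SE over mice; 1.43 within the low-18S pair and 0.89 between the other mice), with adjusted p = 0.00107 and adjusted p = 0.371 with an estimated correlation (alternatives ranged from 4.78e-06 to 0.371). The mean per mouse, centred on all 6, was -1.05 in control mouse 1 against -0.41 and -0.14 in the other controls, and the difference without control mouse 1 was 0.81. Clic6 and Tmem212 rose and 4 did not pass, with 4 past the threshold adjusted over the list alone. Dynlrb2 measured 1.52 ± 0.38 (adjusted p = 0.0999). Markers of leptomeningeal fibroblasts measured 0.71 ± 0.33 over 5 genes (0.51 within the low-18S pair, 0.82 between the other mice), none past the threshold over all genes or adjusted over the list alone, with list adjusted p = 0.0429 and adjusted p = 0.494 with an estimated correlation (alternatives ranged from 0.000185 to 0.494). The leptomeningeal call was lost without control mouse 1 (adjusted p = 0.072), control mouse 5 (0.0829), ZnR mouse 7 (0.0705) or ZnR mouse 11 (0.135).

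Astrocyte, oligodendrocyte and oligodendrocyte precursor lists passed as higher, none of them with an estimated correlation (adjusted p = 0.371, 0.559 and 0.371), and microglia did not pass. Of 9 astrocyte markers, the intermediate filament gene Gfap rose 1.73-fold (0.79 ± 0.10 SE, adjusted p = 0.0214), 8 did not pass and 3 rose adjusted over the list alone. The list mean was 0.25 ± 0.04 (0.31 within the low-18S pair, 0.21 between the other mice), with adjusted p = 0.0125 and adjusted p = 0.371 with an estimated correlation (alternatives ranged from 0.00316 to 0.371). Oligodendrocyte genes had a mean of 0.38 ± 0.21 over 9 markers, within 2 standard errors of 0 (0.34 within the low-18S pair, 0.39 between the other mice), none past the threshold over all genes or adjusted over the list alone, with list adjusted p = 0.0117 and adjusted p = 0.559 with an estimated correlation (alternatives ranged from 6.78e-06 to 0.559). Their mean per mouse, centred on all 6, was 0.53 in ZnR mouse 11, 0.22 in ZnR mouse 3 and -0.18 in ZnR mouse 7, against -0.27 to -0.13 in controls. Without ZnR mouse 11 the difference was 0.21 and the call was lost (adjusted p = 0.105). Oligodendrocyte precursor markers had a mean of 0.29 ± 0.08 over 7 genes (0.27 within the low-18S pair, 0.30 between the other mice), none past the threshold over all genes and 4 higher adjusted over the list alone, with list adjusted p = 0.0289 and adjusted p = 0.371 with an estimated correlation (alternatives ranged from 0.00897 to 0.371). That call was lost without control mouse 1 (adjusted p = 0.0621), control mouse 5 (0.0704) or ZnR mouse 11 (0.0948). The astrocyte call was lost without control mouse 1 (0.0621). Microglia (mean -0.06, adjusted p = 0.268), endothelial cells (0.09, 0.568), mural cells (0.25, 0.271) and interneurons (-0.03, median 0.0015, test directed lower, 0.904) did not pass as lists. The microglia mean was -0.10 without ZnR mouse 3 and -0.03 without control mouse 1, and the endothelial mean was 0.16 without ZnR mouse 7 and 0.06 without ZnR mouse 11. Adjusted over the list alone, 3 mural genes were higher and 1 lower, and likewise 3 and 1 of the interneuron genes. Within the interneuron list Vip fell 2.00-fold (adjusted p = 0.0208), and the GABA transporter gene Slc32a1 measured 0.56 ± 0.11 (adjusted p = 0.0607).

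**Figure D3:**
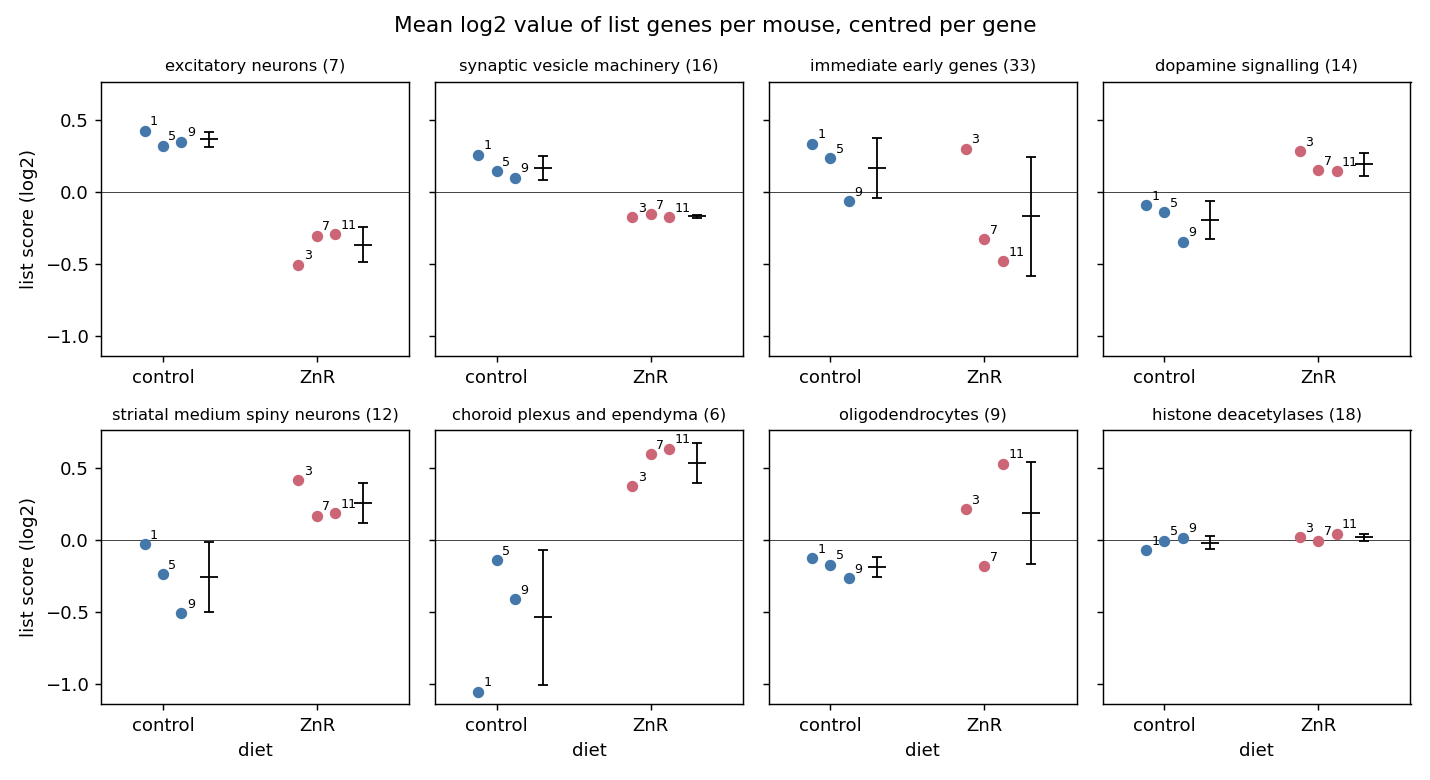
Mean log2 value of a list's genes in each mouse, after subtracting each gene's mean over the 6 mice, for 8 lists by diet. Points are mice with their numbers, and the cross bars show the diet mean ± SD (n = 3); excitatory neuron scores do not overlap between diets, immediate early gene scores do, and oligodendrocyte scores in ZnR mice run from -0.18 to 0.53.

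Histone deacetylase genes did not pass the test for a difference by diet. None of the 18 measured deacetylases and sirtuins passed, over all genes or adjusted over the list alone, and the list mean was 0.04 ± 0.03 (SE over mice, adjusted p = 0.735). The mean was 0.01 without control mouse 1. This list too was chosen from the series title. Hdac1 measured 0.27 ± 0.08 (adjusted p = 0.15) and Sirt4 0.31 ± 0.10 (adjusted p = 0.182), while Hdac2 measured 0.05 ± 0.08 and Hdac3 -0.06 ± 0.08. The 14 histone acetyltransferase genes had a mean of 0.09 ± 0.02 (adjusted p = 0.377) and none passed by either count; Crebbp measured -0.08 ± 0.08, and 2 of its 4 probe sets went the other way. Without ZnR mouse 11 Crebbp measured -0.04 and Hdac3 -0.10, and without control mouse 5 Hdac2 measured 0.03.

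Among zinc handling genes 1 passed the threshold. Of 24 measured transporters, metallothioneins and Mtf1, Slc30a3 fell and 23 did not pass, with Slc30a3 alone past the threshold adjusted over the list alone. The list mean was 0.01 ± 0.03 (adjusted p = 0.735). Excitatory neuron markers were lower by a mean of -0.73 in the same arrays. Whether the fall of Slc30a3 goes beyond that of these markers was not tested. The metallothionein genes Mt1 (0.30 ± 0.08, adjusted p = 0.119), Mt2 (0.28 ± 0.10, adjusted p = 0.215) and Mt3 (0.15 ± 0.08, adjusted p = 0.41) did not pass. The zinc exporter gene Slc30a1 measured 0.02 ± 0.09, with another probe set at -0.10.

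Neuropeptide genes went both ways. Of 14 measured, Cck (-1.04 ± 0.08 SE, adjusted p = 0.00624), Adcyap1 and Vip fell and 11 did not pass, while adjusted over the list alone 5 fell and 2 rose. The list mean was -0.11 and the median 0.0082, and the test, directed lower, gave adjusted p = 0.0525 (alternatives ranged from 5.68e-05 to 0.411). The list passed without ZnR mouse 3 (0.0314) or ZnR mouse 7 (mean -0.16, 0.0483), and its mean was -0.03 without ZnR mouse 11. The serotonin receptor gene Htr1f fell (-0.98 ± 0.12 SE, adjusted p = 0.0208) while the serotonin and noradrenaline receptor list did not pass (mean 0.16, adjusted p = 0.394; 4 higher and 2 lower adjusted over the list alone). Glutamate receptor genes were slightly lower (mean -0.13 ± 0.04 over 19 genes, -0.17 within the low-18S pair and -0.10 between the other mice, adjusted p = 0.0443, and adjusted p = 0.371 with an estimated correlation (alternatives ranged from 0.0139 to 0.371)), with none past the threshold over all genes or adjusted over the list alone, and the call was lost without control mouse 1 (0.0639), ZnR mouse 3 (0.0951) or control mouse 9 (0.116), without the low-18S pair (0.0954), with array weights (0.112) and with the trend and robust prior (0.0608). In the same arrays the excitatory neuron markers were lower by a mean of -0.73 and synaptic vesicle genes by -0.34. Ribosomal protein genes were slightly higher (mean 0.12 ± 0.04 over 18 genes, 0.18 within the low-18S pair and 0.08 between the other mice, adjusted p = 0.0248, and adjusted p = 0.532 with an estimated correlation (alternatives ranged from 0.00123 to 0.532)), with none past the threshold by either count, and the call was lost without control mouse 1 (0.0639), ZnR mouse 3 (0.0613) or control mouse 9 (0.0595), without the low-18S pair (0.13) and with array weights (0.0815).

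The remaining lists did not pass the test. Synaptic plasticity signalling had a mean of -0.09 (adjusted p = 0.0685), with Bdnf and Nrgn (-0.58 ± 0.09 SE, adjusted p = 0.0325) lower among 15 genes; adjusted over the list alone 2 were lower and 1 higher. That list passed without ZnR mouse 11 (mean -0.13, 0.0178; alternatives ranged from 0.00569 to 0.532), and its mean was -0.05 without ZnR mouse 7 or control mouse 9. Heat shock and chaperone genes measured 0.13 (0.0655), with 2 higher and 1 lower adjusted over the list alone. They passed without control mouse 5 (0.0222) or ZnR mouse 11 (0.041; alternatives ranged from 0.0222 to 0.564). The remaining means, with no gene past the threshold by either count, were 0.10 for antioxidant genes (0.192), 0.06 for oxidative phosphorylation genes (0.192) and 0.07 for glucocorticoid-responsive genes (0.735). Oxidative phosphorylation passed with the mean-variance trend (0.028; alternatives ranged from 0.028 to 0.704), and the glucocorticoid mean was 0.02 without ZnR mouse 11 and 0.12 without ZnR mouse 3. GABA receptors measured 0.0003 with a test directed lower (0.562) and clock genes -0.0058 with a median of 0.0085 (0.696).

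In all, 13 of 30 lists passed with the preset correlation of 0.01, 8 higher and 5 lower, and the same 13 passed with the low-18S pair as a block. Some genes are in more than 1 list, among them Bdnf (activity and plasticity), Vip (neuropeptides and interneurons) and Slc17a7. No list passed with a correlation estimated per list, where 3 had an unadjusted p under 0.05. With fry, a rotation test of whether a list's genes move on balance 1 way, 5 passed. The estimated correlation was close to the preset for glutamate receptors (0.0127), oligodendrocyte precursors (0.0164), upper layers (0.0235) and excitatory neurons (0.0373). It ran up to 0.8595, for oligodendrocytes. Where it was close to the preset, the loss of the call cannot be put down to gene correlation alone. For excitatory neurons, at 0.0373, the camera adjusted p went from 5.21e-07 to 0.204. Such a rise is no evidence that gene correlation undid the call, and what else raised it was not tested.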

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

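The tests on the low-18S pair, on consecutive mice and on the added lists were chosen after seeing the data. The count of 373 probe sets was 916 with a mean-variance trend, 904 with trend and robust prior, 2003 with array weights, 3 with unmoderated statistics (3963 at an unadjusted p under 0.05), 1 without the low-18S pair and 1 to 109 with each mouse left out; fewer arrays lower the count by construction, and the other causes were not tested. It stayed between 381 and 550 with no or a stricter level filter, renormalization, median centring, 1 probe set per gene, single-gene probe sets or the low-18S pair as a block. Of the 373, the calls shared were 366 with the trend, 373 with array weights, 363 with no filter, 273 with the stricter filter, 355 after renormalization, 361 after centring, 339 with single-gene probe sets, 360 with the low-18S block and 226 with 1 probe set per gene, where filters and units leave probe sets out by construction. The 13 lists became 0 with an estimated correlation, 5 with fry and 8 to 13 with each mouse left out; the other alternatives gave 11 to 17, and the cause was not tested. With the 4 added lists, 18 passed. No called list and none of the 40 called named genes changed direction under any alternative. For the genes, leaving out mice could not change it, since their mice did not overlap between the diets. The level filter and the variance prior do not alter a probe set's difference. Results that changed direction were all short of the threshold, and the cause was not tested. With array weights the zinc list was -0.0162, deep layers -0.0124, Pecam1 -0.0244, Th -0.0725, Npas4 0.361 and Slc30a1 -0.0076. With probe sets averaged the zinc list was -0.0109, GABA receptors -0.0262, the clock list 0.0007 and Slc30a1 -0.0402. GABA receptors were -0.0099 with median centring and -0.0162 without the low-18S pair, and Th was -0.0061 with quantile normalization. With each mouse left out, the zinc list ran from -0.0097 to 0.0316, GABA receptors from -0.0181 to 0.0212, the clock list from -0.0705 to 0.0476, deep layers from -0.139 to 0.145, interneurons from -0.115 to 0.0371, Th from -0.16 to 0.167, Npas4 from -0.676 to 0.258 and Slc30a1 from -0.0493 to 0.0683. The labels pair no mice. With consecutive mouse numbers (1 and 3, 5 and 7, 9 and 11) as a block, 235 probe sets passed, 180 of them among the 373, as did the same 13 lists and 30 of the 40 called named genes. Deviations from the diet means correlated at 0.311, -0.13 and 0.242 across probe sets in these pairs, and mouse 5 correlated best with mouse 3. The stricter filter left too few ependymal, leptomeningeal, endothelial and mural genes to test. Signal near the background, at a filter level of 4, limits the size of rises from control means of 4.17 (Tmem212), 4.38 (Cfap126), 4.41 (Ube2c) and 4.64 (Dnaic2), and of falls to ZnR means of 4.31 (Smoc2), 4.61 (Cpne9) and 4.75 (Tnnc1).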

Other observations

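The tests on deep layers, on astrocytes against microglia and on splits of the probe set count, and all 4 lists in the next paragraph, were chosen after the results they bear on were seen. The tests on striatal tissue, on neuroblasts and on splits of the list count were written before their own results were seen.

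Further gene lists passed as higher along with the ventricle-lining markers, none with an estimated correlation. Of 22 measured genes of motile cilia, the beating hairs of ependymal cells, 7 rose and 15 did not pass, with a mean of 0.55 ± 0.12 log2 units (SE over mice, n = 3 per diet). Of 25 cell cycle genes, Ube2c (0.94 ± 0.11 SE, limma adjusted p = 0.0204) and Cdc20 (0.70 ± 0.10 SE, adjusted p = 0.0259) rose, named after their values were seen, and 23 did not pass, with a mean of 0.48 ± 0.12. Genes of subventricular neuroblasts, young neurons born beside the ventricle, had a mean of 0.35 ± 0.13 over 9 genes, and markers of septal neurons 0.86 ± 0.36 over 9, none of either past the threshold. Without control mouse 1 these means were 0.23 ± 0.07 and 0.55 ± 0.30, and without control mouse 5 they were 0.38 ± 0.21 and 0.87 ± 0.61, with all but the first within 2 standard errors of 0. Within the low-18S pair they were 0.53 and 1.26, and between the other mice 0.26 and 0.65. Adjusted over the list alone, 16, 18, 3 and 6 genes of the 4 lists were higher. Of the septal markers, Lhx8, named after its value was seen, measured 1.56 ± 0.36 (adjusted p = 0.0829). The 4 lists had camera adjusted p = 5.52e-09, 6.08e-09, 0.0113 and 0.000457 in this order, and adjusted p = 0.352, 0.352, 0.44 and 0.476 with an estimated correlation.

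Dopamine signalling genes were higher on the ZnR diet, and a hypothesis is that the ZnR samples held more striatal tissue. With the mean of 8 striatal markers outside the dopamine list as a covariate, the diet difference of the list mean went from 0.39 ± 0.09 to 0.0998 ± 0.069 (SE, 3 residual degrees of freedom), under the bound of 0.5 of its first value set beforehand. It was -0.0039 ± 0.11 without control mouse 1 and, over 2 standard errors, 0.125 ± 0.033 without control mouse 5 and 0.145 ± 0.066 without control mouse 9. This is consistent with more striatal tissue (Ppp1r1b, an abundant striatal gene, stood at 11.02 in control and 11.63 in ZnR mice), but the covariate itself differed by diet (0.42 ± 0.12), and Penk, Tac1 and Pdyn among its genes respond to dopamine. An effect of diet on striatal-type genes within the tissue stays open and was not tested.

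Cortical excitatory neuron genes were lower and ventricle-lining genes higher on the ZnR diet. Fewer cortical neurons with every other cell type rising alike is argued against only weakly, by a test chosen after these list means were seen. The astrocyte list lay 0.302 ± 0.084 above that of microglia, and 0.234 ± 0.095 above it without Gfap. Without Gfap it was within 2 standard errors of 0 when control mouse 5 (0.256 ± 0.134), ZnR mouse 7 (0.201 ± 0.117) or ZnR mouse 11 (0.205 ± 0.119) was left out. A change in astrocytes themselves stays open. A smaller share of all cortical layers stays open. The 4 deep-layer markers that striatum is not known for were Fezf2, Ccn2, Hs3st4 and Nxph4, the last near the background. They measured -0.26 ± 0.19 (-0.10 without control mouse 1, -0.41 without control mouse 9), within 2 standard errors of 0. They lay 0.0235 ± 0.24 above the upper-layer list (0.23 and -0.17 without these mice). More ventricle-lining tissue in the ZnR samples stays open too: neuroblast genes, not looked at before, were higher by 0.348 ± 0.128, more than 2 standard errors, but by 0.23 ± 0.07 without control mouse 1, and by 0.38 ± 0.21, within 2 standard errors of 0, without control mouse 5. A dissection that reached deeper could give this pattern, but its depth is not given in the sources used here. An effect of the diet on the same cells stays open. The diet and any difference of dissection between the groups cannot be told apart with these samples.

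The counts were set against other splits of the mice. The 6 mice allow 10 splits of 3 against 3, too few for a share under 0.05. The split by diet alone (1 of the 10) gave as many as 373 probe sets, and the highest of the other splits gave 0. For gene lists the split by diet alone (1 of the 10) gave as many as 13, and the highest of the others gave 8.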
